A study of Mus musculus with 4 samples.

How the data were processed

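Total RNA from mouse kidney, taken 2 weeks after bile duct ligation (BDL) or a sham operation, was measured on 4 arrays, 2 per group, with 1 sample per array. BDL ties off the common bile duct and is a surgical model of cholestasis. The samples were grouped by their labels, and the series' design text calls the replicates biological. Each RNA was labelled with Cy3 and hybridised alone, per the labels' protocols.

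Spots were read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. The deposited processed signal is an intensity on a linear scale, background-subtracted and spatially detrended but not scaled between arrays, per the file headers. The median spot signal and the median local background are raw intensities, per the file headers, and the other deposited columns used are flags for control, saturated, outlying and well above background spots. All 4 arrays lay on 1 slide with 1 scan time, so a slide or scan block could not be fitted. The authors' deposited value table holds intensities too. Set against the scanner values, each of its columns was the processed signal divided by 1 constant per array, 709 and 844 for the sham arrays and 739 and 939.8 for the BDL arrays. The column medians of that table were 0.328, 0.339, 0.329 and 0.330 in the same order. Its scale is linear and it is not centred per gene, while the quantity each constant was set on stays unknown.

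The main values were the log2 processed signal minus each array's 75th percentile over all probes, a percentile of 712 and 849 signal units on the sham arrays and 741 and 945 on the BDL arrays. Control spots and spots with an outlier flag were left out, saturated spots would have been kept but numbered 0, and spots of 1 probe were averaged on the log2 scale. Of 55681 probes, 13 had no unflagged spot on at least 1 array and were dropped. The array files hold accessions in place of gene symbols. These were matched without versions to a RefSeq gene table of GRCm38.p6, used only for names and for which genes neighbour each other, because the array grid lists mm9. The match named 27229 of the 55668 analysed probes (20656 symbols), and the other 28439 kept the files' own names. A probe was retained where it was well above background on both arrays of at least 1 group, which left 32280 probes. Of several probes of a gene, the retained probe with the highest mean signal was used, which gave 24043 features, 15022 of them with a symbol. On the 4 arrays, 57.7% and 62.1% (sham) and 59.1% and 63.1% (BDL) of the spots were well above background. With 2 arrays per group, the number of arrays limits the precision of every value.

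BDL and sham were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, operation as the only term), with Benjamini-Hochberg adjustment over all 24043 features and a threshold of 0.05. Intervals are 95% intervals from the same fit. An exact permutation test of 2 against 2 arrays cannot go below a two-sided p of 0.333 and was not used. Where a gene was not well above background on any array of a group, its difference is given as a bound ("at least"): the mean of the brighter group against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background. Where the dimmer group was well above background on part of its arrays, the number of arrays is given. Probes of closely related genes can share targets, so values of such families are uncertain.

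Before the data were examined, 38 gene lists for the tissue and the operation were fixed, as were the rule for naming genes and the alternatives. The lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 38 lists. Each was tested again with a correlation estimated from the residuals and with fry, a rotation test of whether the genes of a set move on balance one way. Of 816 list entries, 726 were measured. Named are Abcc6 with all of its probes, the 12 features higher and the 12 lower in BDL with the smallest p, an informative symbol and no overlap between the groups (all short of the threshold, since none passed it), and up to 4 members of each list with the smallest p. Not every gene that the rule takes is reported here. Genes named outside this rule were chosen after their values were seen, which is said where they appear.

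The fit was tested on simulated data made from the means of these 24043 features, with 200 genes changed in each of 10 simulations of 2 against 2 arrays. Variances were drawn from the distribution that limma fitted, and every gene varied independently of the others. No gene changed by 2-fold was recovered at the threshold, while 6.2% of those changed 4-fold, 60.4% of those changed 8-fold and 79.4% of those changed 16-fold were, with 5.6 false calls per simulation. A simulated list of 20 members shifted by 0.5 on the log2 scale was called in 10 of 10 simulations with the preset correlation and in 8 with an estimated one, and an unshifted list in 0. Lists were called there at an unadjusted p under 0.05. With independent genes, the 0 says nothing about false calls among lists whose genes vary together.

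Alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median, the authors' deposited value table, no filter on dim probes or a filter on all 4 arrays, all retained probes, a variance trend with robust estimation, the replicate number as a block, other thresholds, and leaving out each array in turn. The normexp alternative used the median spot signal, since a mean spot signal was not among the columns used here. Alternatives added after seeing the data were a fit of named features only, the other Abcc6 probe and array weights.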

Results

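Kidney RNA of mice was profiled 2 weeks after bile duct ligation (BDL), which blocks the flow of bile from the liver, or after a sham operation, with 2 animals per group on 1-colour arrays. Between 57.7% and 63.1% of the spots on each array were well above background and 0 were saturated. Values are log2 signals relative to the 75th percentile of the same array, and differences are BDL minus sham. Across the 24043 features, the arrays correlated pairwise with Pearson's r between 0.974 and 0.985 (across genes, which are not independent replicates). The 2 sham arrays (r = 0.979, 2388 features over 2-fold apart) were less alike than the 2 BDL arrays (0.983, 1370). Sham replicate 2 was closer to BDL replicate 2 (0.985, 1428) and BDL replicate 1 (0.979, 1989) than to sham replicate 1.

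The first question, named in the title of the series, concerned ABCC6 and the handling of drugs by the kidney in cholestasis. Abcc6, an ABC transporter of the basolateral membrane that takes part in ATP release and the control of calcification, had nearly the same level in both groups, 0.91 ± 0.40 in sham and 0.90 ± 0.05 in BDL kidneys (log2 signal, SD, n = 2). The difference was -0.01 (SE 0.27, limma adjusted p = 0.995), with a 95% interval from -0.72 to 0.69, or from 0.609-fold to 1.61-fold. A fall of up to that size was not excluded by this probe, the brighter one of the gene. The series title names a decrease of ABCC6, and neither probe of the gene passed the threshold. The other probe gave -0.30 (SE 0.29, adjusted p = 0.897 over all retained probes), which leaves room for a larger fall. The sign of the small difference depended on the array left out, from -0.30 without sham replicate 1 to 0.27 without sham replicate 2.

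Of the 12 ABC drug transporters listed, 11 were measured and none passed the threshold, over all genes or adjusted over the list alone (0 members each). Abcb1a, which encodes a P-glycoprotein that exports many drugs, was 2.72-fold higher in BDL (1.44 log2, SE 0.68, adjusted p = 0.872), with values of 0.23 and -0.89 on the BDL arrays and of -2.59 and -0.97 on the sham arrays, so that most of the difference lay with 1 array of each group. Abcc4 differed by 0.23 (SE 0.21) and Abcc10 by -0.33 (SE 0.19), each without overlap between the groups. Abcc3 differed by 0.98 (SE 0.85) with BDL replicate 1 alone high, and by -0.23 without that array. Abcb11, the bile salt export pump of hepatocytes, was not well above background in either group. The list as a whole had a median difference of 0.05 (camera adjusted p = 0.438), and of -0.01 in the authors' deposited table. That median was -0.12 without sham replicate 1 (adjusted p = 0.517) and 0.36 without sham replicate 2 (adjusted p = 0.0671).

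**Figure D1:**
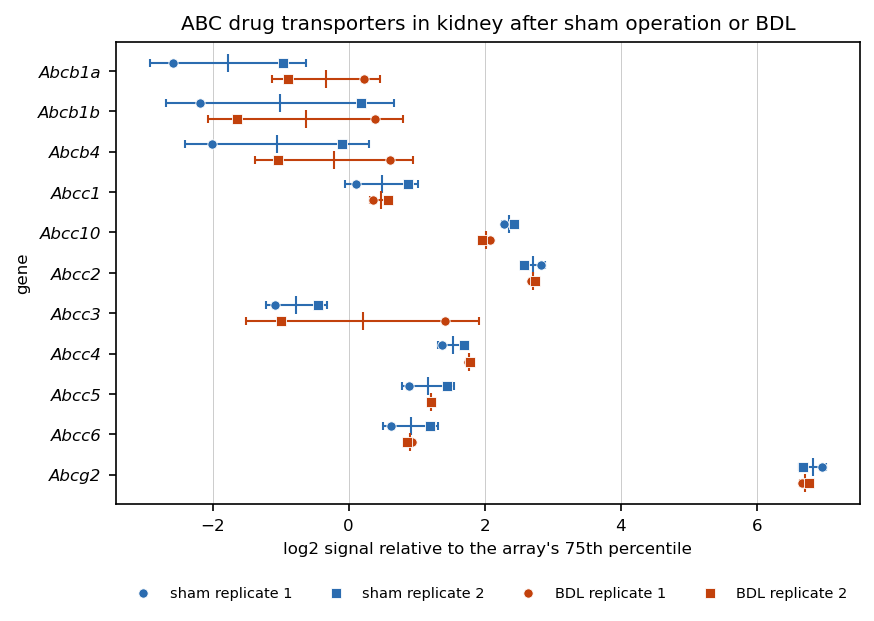
Log2 signal relative to the 75th percentile of each array (horizontal axis) of 11 ABC drug transporters (vertical axis) in sham (blue) and BDL (orange) kidneys. Each point is 1 array, and ticks with bars are the group mean and SD (n = 2). Abcc6 lies at 0.91 in sham and 0.90 in BDL kidneys.

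Organic ion and drug transporters of the SLC families were on balance lower in BDL, in 21 of 29 measured members, with a median of -0.22 (camera adjusted p = 0.0114, and adjusted p = 0.551 with an estimated correlation). Slc22a7, an organic anion transporter of the proximal tubule, was 3.64-fold lower (-1.86, SE 0.54), Slc22a19 was 2.00-fold lower (SE 0.22 log2) and Slc17a3, a urate and phosphate transporter, 1.65-fold lower (-0.72, SE 0.25). Slc22a8, which encodes OAT3 at the basolateral membrane, went the other way, 1.74-fold higher in BDL (0.80, SE 0.22). None of the members passed over all genes (adjusted p of at least 0.759 for these genes), and 0 passed adjusted over the list alone. The list's median was -0.07 without sham replicate 1 (camera adjusted p = 0.222), and its call was also lost without BDL replicate 1 (adjusted p = 0.0756).

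Among the genes for bile acid handling, the basolateral exporter Slc51a/Slc51b stood higher in BDL, with Slc51b at 2.32-fold (1.22, SE 0.27, adjusted p = 0.759) and Slc51a at 2.02-fold (1.01, SE 0.43, adjusted p = 0.872). Slc51a was 5.69 and 5.48 on the BDL arrays, against 5.14 in sham replicate 1 and 4.01 in sham replicate 2. Cyp7b1, an oxysterol hydroxylase of the alternative route of bile acid synthesis, was 3.71-fold lower (-1.89, SE 0.43, adjusted p = 0.759), and Slc27a5 differed by 0.40 (SE 0.24). These 4 genes did not overlap between the groups, which chance gives for 33.3% of genes, and 0 of the 14 measured members passed over all genes and 0 adjusted over the list alone, where Slc51b and Cyp7b1 both stood at 0.0619. Cyp7a1, the rate-limiting enzyme of classical bile acid synthesis, was not well above background in either group, nor were Cyp8b1, Baat, Sult2a1, Fabp6 and Fgf15. The list's median was -0.11 and its mean -0.01, while the test pointed upward (camera adjusted p = 0.867), and the median turned to 0.07 without sham replicate 1 and to 0.07 without BDL replicate 2.

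The second question was which genes differed between BDL and sham kidneys anywhere on the array. The 24 genes below stood out most but fell short of the threshold. Higher in BDL were Cyp27b1, the renal enzyme that makes active vitamin D, by 16.4-fold (4.04, SE 0.46, adjusted p = 0.374), Cyp26b1, which degrades retinoic acid, by 5.54-fold (2.47, SE 0.23), F13a1, the A subunit of coagulation factor XIII, by 5.41-fold (2.43, SE 0.25), Pop4, a subunit of ribonuclease P, by 5.19-fold (2.38, SE 0.19), and Pam, a peptide-amidating enzyme, by 3.18-fold (1.67, SE 0.19). Saa3, an acute phase serum amyloid, was at least 2.38-fold higher, since it was not well above background on either sham array. The same held for the neuropeptide gene Npw (at least 4.22-fold), Lrrc52 (at least 3.53-fold), Ptf1a (at least 2.48-fold), the serotonin receptor gene Htr1a (at least 2.31-fold), Clic6 (at least 2.24-fold) and B3gnt3 (at least 1.38-fold).

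Lower in BDL were Nipal2 by 7.65-fold (-2.94, SE 0.24), Akr1c6, a hydroxysteroid dehydrogenase, by 4.73-fold (-2.24, SE 0.19), Ccdc150 by 3.72-fold (-1.89, SE 0.20), the clock repressor Nr1d1 by 3.57-fold (-1.84, SE 0.23), the water channel gene Aqp8 by 3.34-fold (-1.74, SE 0.25), Hs6st2, a heparan sulfate sulfotransferase, by 3.05-fold (-1.61, SE 0.22) and Hsd17b13, a lipid droplet enzyme, by 3.04-fold (-1.60, SE 0.19). Members of the Xlr family were lower as well, Xlr4b by 7.53-fold (-2.91, SE 0.19, adjusted p = 0.198), Xlr4a by 7.57-fold (-2.92, SE 0.26, well above background on 1 of the 2 BDL arrays) and Xlr3a by at least 2.07-fold. These genes are close copies of each other, and their separate values are uncertain. The transcription factor genes Gata4 (at least 1.75-fold) and Phox2a (at least 1.29-fold) were not well above background on either BDL array. Further probes of Nipal2 (-2.24), Xlr4a (-2.39) and Hsd17b13 (-1.09) had the same sign.

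**Figure D2:**
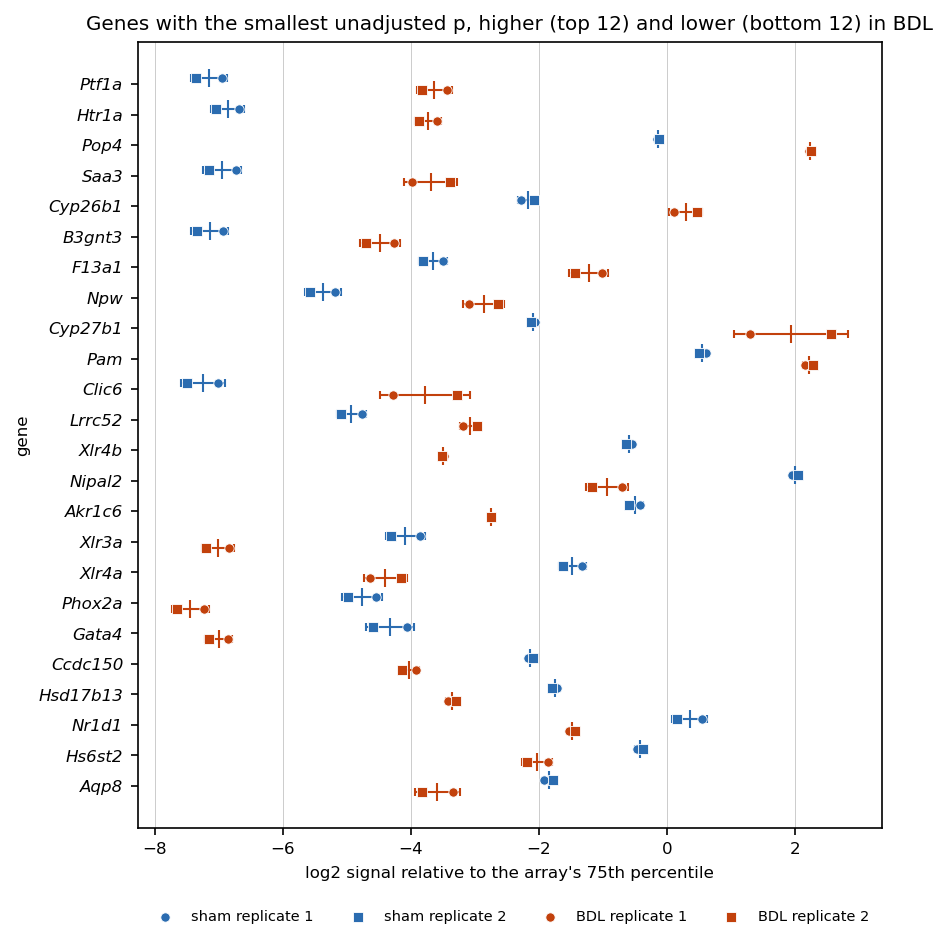
Log2 signal relative to the 75th percentile of each array (horizontal axis) of the 12 genes higher and the 12 genes lower in BDL with the smallest unadjusted p (vertical axis), in sham (blue) and BDL (orange) kidneys. Each point is 1 array and ticks with bars are the group mean and SD (n = 2). Pop4 lies 2.38 apart between the groups, and the lowest signals well above background lie between -5.33 and -4.70 on the 4 arrays.

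With limma, 0 of the 24043 features passed an adjusted p of 0.05, and the smallest adjusted p was 0.198. At an unadjusted p under 0.05 there were 1352 features, 622 higher and 730 lower in BDL, where 1202 would be expected by chance. Both BDL values lay above both sham values in 4174 features and below them in 4628, together 36.6% of all, where chance gives 33.3%. Of these, 377 were at least 2-fold higher and 493 at least 2-fold lower by their group means.

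The third question was whether groups of related genes moved together. Tubular injury markers were higher in BDL in 24 of 30 measured members, podocyte markers in 14 of 15, red blood cell genes in 9 of 10 and acute phase genes in 23 of 28, while interferon response genes were lower in 27 of 28 and androgen-dependent kidney genes in 13 of 14. Some lists share members and are not separate lines of evidence. The tubular injury list shares C3, Cp, Ccl2, Vcam1, Fga, Fgb and Fgg with the acute phase list and Lcn2 with the neutrophil list. The fibrosis and fibroblast lists share collagen and other genes. With the preset correlation, camera called 20 of the 38 lists, 13 higher and 7 lower in BDL. With an estimated correlation it called 0 (smallest adjusted p = 0.551), and fry called 0 (smallest adjusted p = 0.268). Both rest on the few residual degrees of freedom that 2 arrays per group leave, and have little power after adjustment over 38 lists. Their 0 therefore neither backs nor refutes the 20 calls. Over all lists, 0 members passed over all genes and 13 passed adjusted over the list alone.

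Tubular injury genes had a median difference of 0.54 (camera adjusted p = 2.75e-06, and adjusted p = 0.551 with an estimated correlation). Sox9, a transcription factor of tubule repair, was at least 2.60-fold higher, Timp1, an inhibitor of matrix proteases, 3.16-fold higher (1.66, SE 0.36), complement C3 3.96-fold (1.99, SE 0.70) and the keratin gene Krt8 1.72-fold (0.78, SE 0.23). C3 was 4.95 in BDL replicate 1 and 3.26 in BDL replicate 2, against 2.69 and 1.55 on the sham arrays. None of the members passed over all genes, and 0 passed adjusted over the list alone. BDL replicate 1 was also high in urothelial keratins (below), and without it the list's median was 0.30. Acute phase and cytokine genes had a median of 0.38 (adjusted p = 0.000123, and adjusted p = 0.551 with an estimated correlation), with 2 members past the threshold adjusted over the list alone, Saa3 and the oncostatin M receptor gene Osmr (2.49-fold, 1.32, SE 0.19). Lrg1 was 2.94-fold (1.56, SE 0.32) and Socs3, a feedback inhibitor of cytokine signalling, 3.09-fold higher (1.63, SE 0.43) without passing. Without sham replicate 2 the acute phase median was 0.25 and the call was lost (adjusted p = 0.160).

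Podocyte genes had a median of 0.47 (adjusted p = 1.85e-07, and adjusted p = 0.551 with an estimated correlation). Wt1, a podocyte transcription factor, was 1.95-fold higher (0.97, SE 0.20), Cdkn1c 2.94-fold (1.56, SE 0.34), Plce1 2.23-fold (1.16, SE 0.29) and Podxl, which encodes podocalyxin, 1.69-fold (0.76, SE 0.20), each at 0.0550 adjusted over the list alone, where 0 passed. Markers of intercalated cells, the acid-base cells of the collecting duct, were higher in 15 of 16 members with a median of 0.32 (adjusted p = 0.000130, and adjusted p = 0.551 with an estimated correlation), and the median was 0.55 without sham replicate 2. Slc26a4, which encodes pendrin, was 1.76-fold higher (0.82, SE 0.26) and Slc4a9 1.70-fold (0.76, SE 0.23). Genes of the distal convoluted and connecting tubule had a median of 0.29 (adjusted p = 0.00635, and adjusted p = 0.635 with an estimated correlation), among them the calcium channel gene Trpv5 (2.17-fold, 1.12, SE 0.29) and the thiazide-sensitive transporter gene Slc12a3 (1.99-fold, 0.99, SE 0.37). This call was lost without sham replicate 2 (median 0.10, adjusted p = 0.490), and the median was 0.57 without sham replicate 1.

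Endothelial genes had a median of 0.27 (adjusted p = 0.00635, and adjusted p = 0.737 with an estimated correlation), with Plat, the tissue plasminogen activator gene, 1.85-fold higher (0.89, SE 0.20). The median was 0.02 without sham replicate 1 (adjusted p = 0.812, direction turned) and 0.47 without sham replicate 2. Fibrosis and matrix genes had a median of 0.14 (adjusted p = 0.0223, and adjusted p = 0.618 with an estimated correlation), with the proteoglycan gene Bgn 1.78-fold (0.84, SE 0.21) and Tgfbi 1.74-fold higher (0.80, SE 0.27). That median was -0.08 without sham replicate 1 (adjusted p = 0.857), 0.42 without sham replicate 2 and 0.02 without BDL replicate 1 (adjusted p = 0.0540). Renin-angiotensin and vasoactive genes had a median of 0.16 (adjusted p = 0.0478, and adjusted p = 0.551 with an estimated correlation), with the vasopressin receptor gene Avpr1a at 1.80-fold (0.85, SE 0.21), Sgk1 at 1.78-fold (0.83, SE 0.24) and Ace 1.54-fold lower (-0.62, SE 0.19). Without sham replicate 1 the median was 0.05 (adjusted p = 0.681), without sham replicate 2 it was 0.30, and without BDL replicate 2 the call was lost (adjusted p = 0.112), as it was with quantile normalization (adjusted p = 0.0704), array weights (adjusted p = 0.0559), only features with a symbol (adjusted p = 0.0721), all retained probes (adjusted p = 0.0542) and no filter on dim probes (median 0.02, adjusted p = 0.104).

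Red blood cell genes had a median of 1.32 (adjusted p = 3.20e-05, and adjusted p = 0.551 with an estimated correlation). The globin gene Hbb-b2 was 3.10-fold higher (1.63, SE 0.22) and Klf1, the erythroid transcription factor gene, 7.13-fold higher (2.83, SE 0.53). These 2 members passed adjusted over the list alone and 0 passed over all genes. BDL replicate 1 was the higher of the BDL arrays, and without it the median was 0.51. Neutrophil genes had a median of 0.87 (adjusted p = 0.00365, and adjusted p = 0.551 with an estimated correlation), with Lcn2 at 2.18-fold (1.12, SE 0.50) and S100a8 at 4.24-fold (2.08, SE 1.08). Lcn2 was 2.31 in BDL replicate 1 and 1.01 in BDL replicate 2, against 0.26 and 0.81 on the sham arrays. Without sham replicate 2, in which S100a8 was lowest, the call was lost (median 0.51, adjusted p = 0.0707), and the median was 0.51 without BDL replicate 1 and 0.54 with normexp. B and plasma cell genes were lower, with a median of -0.84 (adjusted p = 0.00365, and adjusted p = 0.551 with an estimated correlation). Cd79b was 2.04-fold lower (-1.03, SE 0.21) and Ms4a1, which encodes CD20, at least 2.35-fold lower, and these 2 passed adjusted over the list alone. The call was lost without sham replicate 2 (adjusted p = 0.0536) and among genes well above background on all 4 arrays (median -0.28, adjusted p = 0.141), and the median was -0.50 without BDL replicate 1, -0.43 with normexp and -0.46 with no filter on dim probes.

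Interferon response genes had a median of -1.64 (adjusted p = 1.43e-09, and adjusted p = 0.578 with an estimated correlation), and sham replicate 1 carried most of it. That array stood 2.68 above the mean of the other 3 arrays in the median of the list, 0.75 in T and NK cell genes and 1.07 in macrophage and dendritic cell genes. Without it the interferon median was -0.24, and without sham replicate 2 it was -2.76. Ifit2 was 2.14-fold lower in BDL (-1.10, SE 0.21), Ifit3 3.97-fold (-1.99, SE 0.49), Oas2 2.44-fold (-1.29, SE 0.41) and Oas1a by -1.59 (SE 0.45), with no overlap between the groups, while 0 members passed over all genes and 0 adjusted over the list alone. T and NK cell genes had a median of -0.60 (adjusted p = 0.000947, and adjusted p = 0.681 with an estimated correlation), with Cd3g 1.94-fold lower (-0.95, SE 0.35), and 0 members passed either way. That median was -0.27 without sham replicate 1 (adjusted p = 0.563) and -0.33 without BDL replicate 2. Macrophage and dendritic cell genes had a median of -0.11 (adjusted p = 0.748). Without sham replicate 1 their median was 0.48, and without sham replicate 2 it was -0.84. The list was called as higher in the first fit and as lower in the second. Cd14 was 1.75-fold higher in BDL (0.81, SE 0.21) and Csf1r 1.36-fold lower (-0.45, SE 0.19).

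**Figure D3:**
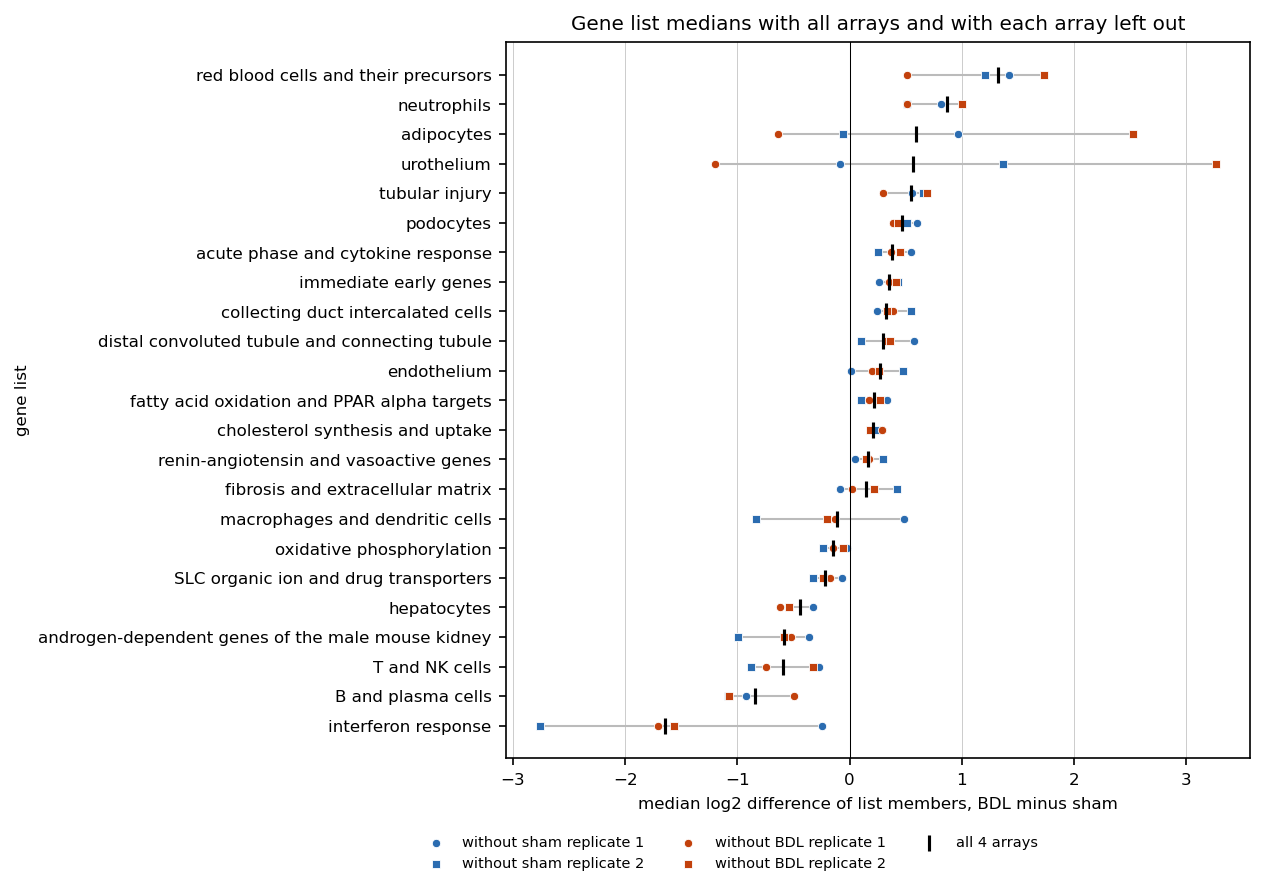
Median log2 difference (BDL minus sham, horizontal axis) of the 20 lists called with the preset correlation, and of the urothelial, adipocyte and macrophage lists (vertical axis). Black ticks use all 4 arrays, points leave out 1 array each (blue, sham; orange, BDL), and grey lines span the points. The interferon median is -1.64 with all arrays and -0.24 without sham replicate 1.

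Androgen-dependent genes of the male mouse kidney were lower in 13 of 14 members, with a median of -0.58 (adjusted p = 3.20e-05, and adjusted p = 0.551 with an estimated correlation). Besides Cyp7b1, the fatty acid hydroxylase genes Cyp4a12b and Cyp4a12a were 3.56-fold (-1.83, SE 0.53) and 3.21-fold lower (-1.68, SE 0.49), and Acsm3 was 1.93-fold lower (-0.95, SE 0.30). None passed over all genes, and 0 passed adjusted over the list alone. The median was -0.36 without sham replicate 1 and -0.99 without sham replicate 2. The 5 genes listed beforehand as female-biased were not tested for such a bias here. Of these, the prolactin receptor gene Prlr was 2.21-fold higher (1.15, SE 0.19) and passed adjusted over the list alone, as 1 member. Slc22a7 and Cyp2a4 (-0.74, SE 0.35) were lower. That list had a median of 0.78 and a mean of 0.03 (adjusted p = 0.438), and the median was -0.17 without BDL replicate 1, 1.11 without BDL replicate 2 and 0.46 with normexp.

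Genes of fatty acid oxidation and PPAR alpha targets had a median of 0.22 (adjusted p = 0.00188, and adjusted p = 0.551 with an estimated correlation). The mitochondrial carnitine carrier gene Slc25a20 was 1.60-fold higher (0.68, SE 0.19), Acot3 3.65-fold (1.87, SE 0.52) and the thiolase genes Acaa1b and Acaa2 1.59-fold (0.67, SE 0.19) and 1.84-fold (0.88, SE 0.26). Without sham replicate 2 the call was lost (median 0.10, adjusted p = 0.140), and without sham replicate 1 the median was 0.34. Genes of cholesterol synthesis and uptake had a median of 0.21 (adjusted p = 0.00484, and adjusted p = 0.551 with an estimated correlation), with Fdps at 1.54-fold (0.62, SE 0.19) and Fdft1 at 1.56-fold (0.64, SE 0.21). The call was lost without sham replicate 2 (adjusted p = 0.0707) and without BDL replicate 2 (adjusted p = 0.227). Genes of oxidative phosphorylation were lower in 24 of 29 members, with a median of -0.15 (adjusted p = 0.0478, and adjusted p = 0.885 with an estimated correlation). Cox5b was 1.72-fold lower (-0.79, SE 0.21). Their median was -0.02 without sham replicate 1 (adjusted p = 0.943), -0.06 without BDL replicate 2 (adjusted p = 0.482) and -0.23 without sham replicate 2, and the call was also lost with quantile normalization (median -0.08, adjusted p = 0.194), no filter on dim probes (adjusted p = 0.113), array weights (adjusted p = 0.0567) and the replicate block (adjusted p = 0.0621).

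Immediate early genes were higher in 15 of 18 members, with a median of 0.35 (adjusted p = 0.000375, and adjusted p = 0.551 with an estimated correlation), among them Fos (2.05-fold, 1.03, SE 0.23) and Nr4a1 (1.70-fold, 0.77, SE 0.24). Circadian clock genes moved in opposite directions and were not called as a list (median 0.16, adjusted p = 0.0794). The list was called without BDL replicate 1 (median 0.31, adjusted p = 0.0165), and its median was 0.05 without sham replicate 1 and 0.31 without sham replicate 2. By gene, 4 of the 16 measured members passed adjusted over the list alone, the most of any list, and 0 over all genes. Nr1d1 and Dbp, which was 2.59-fold lower (-1.37, SE 0.32), were lower in BDL, and Nfil3 (3.50-fold, 1.81, SE 0.33) and Cry1 (at least 2.37-fold) were higher. Transcripts more typical of hepatocytes were lower in 10 of 13 members, with a median of -0.44 (adjusted p = 0.00401, and adjusted p = 0.551 with an estimated correlation), such as the transthyretin gene Ttr (2.35-fold, -1.23, SE 0.28) and the antitrypsin gene Serpina1a (1.88-fold, -0.91, SE 0.30). That call was lost without BDL replicate 2 (adjusted p = 0.0605), and the median was -0.70 with no filter on dim probes and over all retained probes.

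The remaining lists were not called in the main fit. Of the calcification genes (median 0.07, adjusted p = 0.124, with medians of 0.03 without sham replicate 1 and 0.03 without BDL replicate 1), Cyp27b1 and Mgp, an inhibitor of calcification that was 2.28-fold higher (1.19, SE 0.21), passed adjusted over the list alone, as 2 members. Urothelial genes had a median of 0.56 (adjusted p = 0.208) and adipocyte genes of 0.59 (adjusted p = 0.346), and both were high on BDL replicate 1 alone, by 5.30 and 2.66 over BDL replicate 2. Without BDL replicate 1 these medians were -1.20 and -0.64, and without BDL replicate 2 they were 3.27 and 2.52. Both lists were called as lower in the first fit and as higher in the second, so such calls can rest on 1 array. The sham arrays mattered too, with medians of -0.08 and 0.96 without sham replicate 1 and of 1.37 and -0.06 without sham replicate 2. Fibroblast, pericyte and smooth muscle genes had a median of 0.32 (adjusted p = 0.132). They were called without sham replicate 2 (median 0.42, adjusted p = 0.0151) and without BDL replicate 2 (median 0.20, adjusted p = 0.00729), while the median was 0.05 without sham replicate 1 and -0.04 without BDL replicate 1. The loop of Henle genes had a median of -0.30 (adjusted p = 0.0933), which was -0.61 without sham replicate 1 and turned to 0.11 without sham replicate 2. That list was called as lower without sham replicate 1 and with the replicate block (adjusted p = 0.0196). It was also called among genes well above background on all 4 arrays (median -0.32, adjusted p = 0.0386). Markers of collecting duct principal cells had a median of 0.02 (adjusted p = 0.346), between -0.10 without sham replicate 1 and 0.34 without sham replicate 2, with the sodium channel gene Scnn1b at 1.47-fold (0.55, SE 0.21). Cell cycle genes had a median of 0.08 (adjusted p = 0.438). It was 0.38 without BDL replicate 1, where the list was called as higher, and -0.15 without BDL replicate 2. It was 0.24 without sham replicate 1 and -0.09 without sham replicate 2.

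The lists of drug-metabolising enzymes were not called, and the sign of their medians depended on which sham array was left out. Cytochrome P450 and other phase I genes had a median of -0.02 and a mean of -0.04 with a test that pointed upward (adjusted p = 0.902). Cyp1a1 was 2.47-fold (1.31, SE 0.30) and Fmo2 1.71-fold higher (0.77, SE 0.27), while Cyp4a12b (-1.83, SE 0.53) and Cyp4a12a (-1.68, SE 0.49) were lower. The list's median was 0.13 without sham replicate 1 and -0.09 without sham replicate 2. Phase II conjugating enzymes had a median of -0.10 (adjusted p = 0.530), with the glucuronosyltransferase gene Ugt2b5 1.82-fold lower (-0.86, SE 0.30) and Gstm5 1.47-fold higher (0.56, SE 0.20), and the median was 0.15 without sham replicate 1 and -0.35 without sham replicate 2 (adjusted p = 0.0507). NRF2 targets had a median of -0.07 (adjusted p = 0.901), with Gclc, an enzyme of glutathione synthesis, 1.65-fold lower (-0.72, SE 0.23) and Osgin1 1.60-fold higher (0.68, SE 0.23), and the median was 0.14 and -0.27 without sham replicates 1 and 2 in turn. Proximal tubule genes had a median of -0.05 and a mean of 0.02 with a test that pointed upward (adjusted p = 0.919), and a median of 0.03 with quantile normalization, with the sulfate transporter gene Slc13a1 2.49-fold higher (1.32, SE 0.28) and Keg1 1.78-fold lower (-0.83, SE 0.21), and the median was 0.02 and -0.13 without sham replicates 1 and 2 in turn. Genes of ER stress had a median of 0.05 and a mean of 0.02 with a test that pointed downward (adjusted p = 0.981), between -0.12 without sham replicate 2 and 0.12 without sham replicate 1. Adrenal genes, of which 6 of 13 were measured, had a median of -0.11 (adjusted p = 0.901), which was 0.02 in the authors' deposited table and 0.09 without sham replicate 2.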

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

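The fit of named features only, the other Abcc6 probe and the array weights were chosen after seeing the data; the other alternatives were planned. With limma, 0 features passed under every alternative run, also at an adjusted p of 0.10, against 1352 at an unadjusted p under 0.05. That count lay between 844 (without BDL replicate 1) and 2793 (without sham replicate 2) when 1 array was left out, where the lone array of a group is assumed to vary like the others; the cause was not tested. Of 20 called lists, 0 passed with an estimated correlation and 0 with fry; 7 were called in the same direction under every other alternative: tubular injury, interferon response, immediate early, androgen-dependent, intercalated cell, podocyte and red blood cell genes. Abcc6 stayed short of the threshold throughout and changed sign around 0, to 0.033 with normexp and to between -0.30 and 0.27 with 1 array left out; the other probe gave -0.30. As 0 features passed throughout, only signs of named genes could differ, and the 24 leading genes, picked for no overlap, cannot turn when 1 array is left out. Other named genes without overlap cannot turn then either. The variance trend, the replicate block, the array weights and the fit of named features only left the differences unchanged. Many values could therefore not reverse, and their number is no measure of stability. Of 2462 values of the named genes other than Abcc6 under an alternative, 8 reversed. Without BDL replicate 1, the array high in urothelial and adipocyte genes, 5 were lower in BDL, and without BDL replicate 2 they were higher: Abcc3 (-0.23 and 2.19), Fabp4 (-0.37 and 2.08), Lipe (-0.41 and 1.12), Krt20 (-0.58 and 6.04, well above background on 1 of the 2 sham arrays) and Psca (-1.04 and 3.30). Hsd3b1 lay between -0.81 (without sham replicate 1) and 0.11 (without sham replicate 2), at 0.032 without BDL replicate 1, and Trp63 was 0.067 over all retained probes. The deviations of same-numbered arrays correlated at 0.063 across genes. With 2 pairs, this cannot show whether the replicate numbers pair the samples. With the replicate block, 0 features passed, 1448 had an unadjusted p under 0.05, and 20 lists were called, with oxidative phosphorylation lost and loop of Henle gained. Array weights came out equal within each group (0.737 sham, 1.36 BDL) and so could not weigh sham replicate 1 down alone. A slide or scan block was not run, since 1 slide held all arrays. Dim genes are limited by signal over background, and their folds are bounds.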

Other observations

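Further members of the Xlr family, a cluster of closely related genes, and neighbours of leading genes were looked up after the values of the leading genes were seen. Xlr3b was 7.88-fold lower in BDL (-2.98, SE 0.46, limma adjusted p = 0.591) and Xlr5a at least 1.85-fold lower, while Xlr differed by -1.07 (SE 0.44, adjusted p = 0.872). Slco6d1, an organic anion transporter family gene next to Pam, was not well above background in sham kidneys and at least 3.13-fold higher in BDL (adjusted p = 0.503). Akr1c18, next to Akr1c6 and like it a hydroxysteroid dehydrogenase gene, was 4.58-fold lower (-2.19, SE 0.34, adjusted p = 0.591), and the adjoining chloride channel accessory genes Clca3a1 and Clca3a2 were 2.77-fold (1.47, SE 0.25) and 2.87-fold higher (1.52, SE 0.25). Gm8300 was at least 2.14-fold lower and its neighbour Gm2022 2.41-fold lower (-1.27, SE 0.21), but the neighbours Chrdl1 (2.54-fold lower, -1.35, SE 0.24) and Pak3 (at least 2.52-fold higher) went opposite ways. None of these passed the threshold. The Y-linked genes Ddx3y, Eif2s3y and Uty were well above background on all 4 arrays and differed by 0.03 each between the groups.

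The tests of array scaling, of a response shared by both BDL animals, and of a shared probe target were chosen only after the result was seen, and the others before. After the values were seen, these tests were made to require Xlr probes well above background on every array, a gap between the BDL arrays that allows for the difference between the sham arrays (a rule revised more than once), and a Pop4 direction against that of Xlr4b. Igtp, Cfd and Upk1a were picked after their values were seen. Igtp stood 67.1-fold above the mean of the other 3 arrays in sham replicate 1, and the interferon list as a whole 2.68 (95% bootstrap interval 2.09 to 3.25, 28 genes, all above background in both sham kidneys). The median of 12 leukocyte markers was higher there by 0.78 (interval 0.55 to 0.91), and each of these markers was higher. This rise lies below the interferon interval, so a larger share of immune cells by that amount falls short of it. Both intervals cover genes of 1 animal, so the test cannot exclude immune cells as a cause. A shift shared by genes of similar signal falls short too, as 0 of 10000 random lists matched on signal had a median as high (highest 0.33). The values were already scaled per array, which holds such lists near 0, so this is no test of scaling of the whole array. An interferon response in that animal may remain as an explanation, which the design does not name and no test covered.

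BDL replicate 1 exceeded BDL replicate 2 by 5.30 in urothelial genes (interval 2.15 to 6.01) and by 2.66 in adipocyte genes (1.54 to 7.56), with the abundant markers Cfd at 6.41 against -4.19 and Upk1a at 4.68 against -0.35. BDL replicate 2 was not above the sham mean in these genes, so a rise shared by both BDL animals was not seen. The lists were picked because the BDL arrays differed, and each interval covers genes of 1 animal. The values below therefore restate that difference and cannot exclude a response to ligation. Against the sham mean, BDL replicate 2 lay at -1.20 in urothelial (interval -2.55 to -0.61) and -0.64 in adipocyte genes (-2.64 to -0.36), and BDL replicate 1 at 3.27 (2.25 to 3.66) and 2.52 (1.12 to 4.58), further apart than the sham arrays (1.48 and 0.48). Renal pelvis and fat in the tissue sample of BDL replicate 1 may account for the pattern, and further urothelial markers were higher by 1.95 (interval 0.49 to 6.29) and further adipocyte markers by 0.64 (0.04 to 2.42), but both intervals reach below the difference of 1 set in advance, so the test left this open. Of the 12 urothelial and 10 adipocyte genes measured, 10 and 10 were above background in both sham kidneys, BDL replicate 2 lay below both sham arrays in 9 and 8, and 1 urothelial gene (Krt20) is also in the tubular injury list.

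Xlr3a, Xlr4a, Xlr4b and Pop4 lay far apart between the groups and close within them. A shared probe target may account for the Xlr genes, but the span of their differences (0.020) decides nothing, since Xlr3a was not well above background on either BDL array and Xlr4a on only 1 of the 2. Pop4 was higher in BDL by 2.38 (interval 1.88 to 2.87) where Xlr4b was lower (-3.41 to -2.41). These opposite directions were known when the rule was written, so they are no test of a shared target for Pop4. An inherited difference between the animals of the groups that spans linked genes may underlie the pattern. With the Xlr genes left out, the 100 named genes with the smallest p held 5 pairs at most 5 genes apart, where random draws held 3.28 on average and a share of 0.232 held as many, which leaves this open.

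Both other splits of the 4 arrays into pairs gave fewer features at an unadjusted p under 0.05 than the real one (1352), 1115 for replicate 1 against 2 and 687 for the crossed split. With 3 splits, a share under 0.05 cannot be reached.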
